A study of Mus musculus with 16 samples.

How the data were processed

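Bulk RNA-seq was measured in 16 libraries, 1 per tumour, of 2 kinds of transplanted mouse glioblastoma with or without TAM depletion. Per the labels' protocols, RNA was extracted with TRIzol and a miRNeasy Micro kit and libraries were made with the SMART-Seq v4 Ultra Low Input kit. This kit copies full-length cDNA from small inputs and does not mark strand, so reads of a gene and of an overlapping or antisense gene cannot be told apart. Per the submitters' processing notes, reads were aligned with STAR 2.7.8a to GRCm38 and DESeq2 was used. Its version, the counting tool, the annotation and the rule by which low genes were left out are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, and columns were matched to samples by the names the labels give. All per-sample columns were used.

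The authors deposited 3 tables of gene values on a log2 scale, 1 of all 16 libraries (26466 genes), 1 of the 8 Type 1 libraries (30589 genes) and 1 of the 8 Type 2 libraries (26130 genes). The design fixed before the data were examined assumed linear normalized counts, as the table names imply. The deposited log2 values proved to be variance-stabilized instead: each table has 1 lowest value shared by all columns (3.74, 2.39 and 4.87). They were inverted to normalized counts, with v the deposited value, as the square of 2 to the power v/2 minus 2 to the power (floor - v/2). The inverted values were whole multiples of 1 step per library in 100% of values (tolerance 0.05 reads, largest deviation 7.4e-08), which gave the reads and the authors' size factors. The reads recovered from the table of all libraries equalled those from the table of each tumour kind in 100% of shared genes. Values were normalized separately in the 3 tables, so tests were run within 1 table.

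Genes with a normalized count of 10 or more in at least 3 libraries were tested (26463). Differential expression was tested on log2(normalized count + 1) with limma-trend (limma 3.58.1, R 4.3.3) in 1 fit of 4 group means over all 16 libraries (12 residual degrees of freedom, prior 4.74). Tests were 2-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 4 contrasts were TAM depleted against Control in each tumour kind, the difference of these responses, and Type 2 Control against Type 1 Control. The deposited unit is not a count, and a count model was not run, although the recovered whole reads would have allowed one. Limma-voom was run on the recovered reads as an alternative chosen after seeing the data. TAM scores are the mean log2(normalized count + 1) of 24 genes per library, compared with 2-sided exact permutation tests over all splits.

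There were 31 gene lists of cell types and pathways, fixed before the data were examined. Each was tested with camera at a preset correlation of 0.01 and again at an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. P-values were adjusted over the 31 lists of a comparison. Fry passed 0 lists in Type 1, 9 in Type 2, 1 for the difference of responses and 12 between the controls. Genes to name were set beforehand. They were the 10 largest rises and 10 largest falls among genes past the threshold with a mean of 50 or more in the higher group and no overlap between the groups of libraries, leaving out predicted or unnamed gene models. Csf1r, Aif1, Cd68, C1qa, Tmem119, P2ry12 and Ccr2 were named in every comparison. Added were up to 4 members with the smallest p of each list described and the driver genes. Coordinates are those of GENCODE vM21 (GRCm38, 1-based); 25515 symbols (96.4%) had 1 match.

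Depth was 4.21 to 18.3 M recovered reads per library, and 90.5% to 100% of genes had a read. Reads carry no molecular identifiers, so intervals cover counting error only. No pair of libraries of a group was alike within sampling noise (lowest chi-square per degree of freedom 9.43). Replicate numbers are shared between groups, and their check is given with the alternatives. The steps were tested on simulated counts with 50 genes each changed 2-, 4-, 8- and 16-fold. For Type 1 depletion (26450 genes) 8%, 72%, 84% and 92% were recovered, with 14 wrong among 142 calls. For Type 2 depletion (26448 genes) it was 8%, 66%, 86% and 94% (8 of 135). Between the controls (26445 genes) it was 6%, 64%, 94% and 92% (8 of 136), and for the difference of responses (26447 genes) 2%, 20%, 64% and 80% (3 of 86). Changes of 2-fold are therefore mostly out of reach. The simulated counts were drawn for each gene on its own, without the 2 background sets described below. The recovered shares therefore do not carry over to the real libraries. In Type 1, 5543 genes lower at an unadjusted p under 0.05 had a median log2 fold change of -2.60, and 0 genes passed.

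Alternatives were pseudocounts of 0.5 and 8, no filter and a filter of 50, quantile and upper quartile scaling, library quality weights and robust moderation. Others were a replicate block, a minimum log2 fold change of 1, each tumour kind's own table, the controls alone, and each library left out in turn. A block for the number series in the Type 1 sample names was also run. Added after seeing the data were the deposited values as they are, limma-voom, and several treatments of background: a covariate, a block for the background set, subtraction of the reads expected from gene length, and each set alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.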

Results

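Bulk RNA sequencing was carried out on 16 transplanted mouse glioblastomas of 2 kinds, which the labels call Type 1 and Type 2. Part of each kind had been depleted of tumour-associated macrophages (TAMs), the macrophages and microglia that live within a tumour. The groups held 5 Type 1 Control, 3 Type 1 TAM depleted, 4 Type 2 Control and 4 Type 2 TAM depleted tumours. How the TAMs were depleted, the sex of the animals and the cell each tumour kind arose from are not given in the sources used here. The reads recovered from the deposited values ranged from 4.21 to 18.3 M (mega) per library. They averaged 6.32 ± 0.74 M (SD, n = 5) in Type 1 Control and 15.3 ± 0.91 M (SD, n = 3) in Type 1 TAM depleted libraries. In Type 2 they averaged 9.74 ± 4.98 M in Control and 12.2 ± 5.22 M in TAM depleted libraries (SD, n = 4 each). Each library is a separate tumour in the design text, and nothing ties a tumour to an animal, so p-values measure the spread between these samples. Log2 fold changes are those of the normalized count plus 1, which understates the change of low genes.

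The libraries split into 2 sets by their reads in odour and pheromone receptor genes. Reads in the 997 olfactory and vomeronasal receptor genes, which sensory neurons of the nose express, stood above 2500 per M reads in 9 libraries, the lowest at 2717, and at 811 per M reads or less in the other 7. These sets are called high-background and low-background below. The share of reads in Gm10800, a predicted gene, moved with them and ranged from 0.0491% (95% Wilson interval 0.0481% to 0.0501%) in Type 2 TAM depleted 2 to 58.2% (58.2% to 58.3%) in Type 2 Control 1. These intervals cover counting error only. The first principal component of the log2 values held 61.1% of the variance and ran from -217.5 to -35.3 in the high-background and from 52.9 to 228 in the low-background libraries. In Type 1 the sets coincided with the treatment: all 5 controls were high-background and all 3 depleted tumours low-background. Their receptor reads were 4785 ± 789 (SD, n = 5) against 385 ± 175 per M reads (SD, n = 3; 2-sided exact permutation p = 0.0357, the smallest that 56 splits allow). In Type 2 they were balanced, with Control 1 and 3 and TAM depleted 3 and 4 high-background (3650 ± 3900 against 2225 ± 2756 per M reads, SD, n = 4 each; exact permutation p = 0.571).

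**Figure D1:**
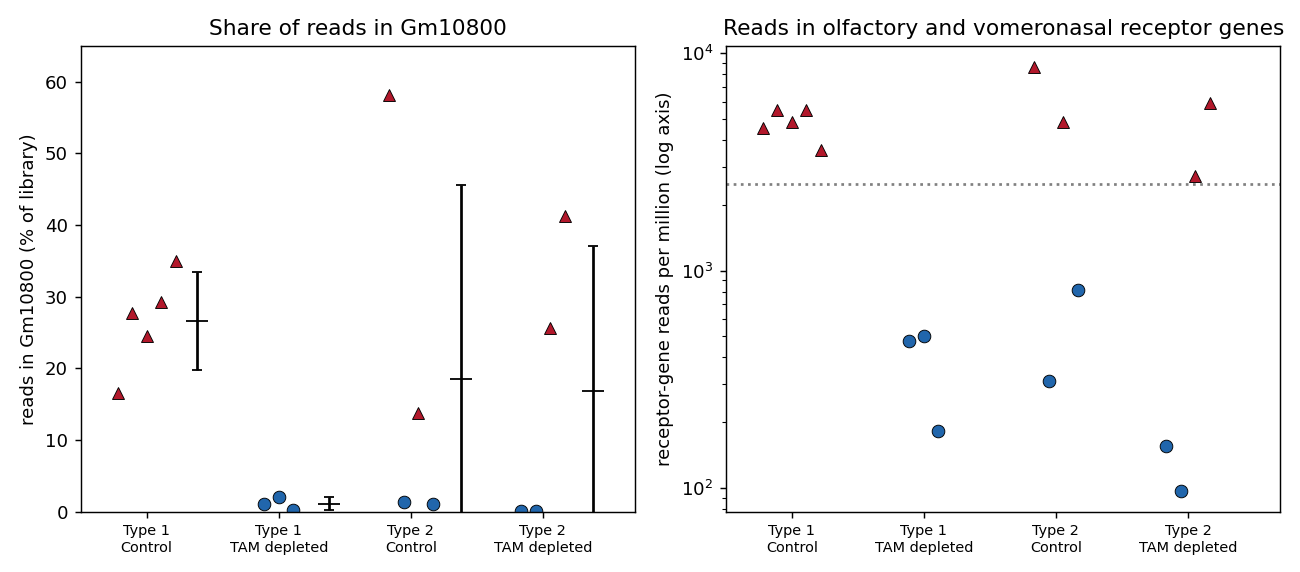
Share of reads in Gm10800 (left, percent of the library) and reads in 997 olfactory and vomeronasal receptor genes (right, per M reads, log axis) in each of the 16 libraries by group. Triangles are the 9 high-background and circles the 7 low-background libraries, bars on the left are mean ± SD (drawn down to 0), and the dotted line marks 2500 per M reads. The 5 Type 1 controls lie above it and the 3 Type 1 TAM depleted libraries below.

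The comparison of Type 2 TAM depleted with Type 2 Control tumours asks which transcripts change in this model when TAMs are depleted. Macrophage transcripts were lower. The mean log2 level of the TAM list, 24 genes expressed by macrophages and microglia, was 7.0 ± 0.54 (SD, n = 4) after depletion and 8.28 ± 0.50 (SD, n = 4) in controls, 2.44-fold lower (2-sided exact permutation p = 0.0286, the smallest that 70 splits allow). Neuronal transcripts rose most. Snap25, a synaptic vesicle fusion protein (chr2:136713453-136782428, GRCm38), went from 416 ± 560 to 6750 ± 5124 normalized counts (SD, n = 4 each), a log2 fold change of 4.58 (SE 0.75, limma-trend adjusted p = 0.00932). The largest falls were in 4 genes of the Y chromosome, followed by Acan, the matrix proteoglycan aggrecan, and Car9, a hypoxia-induced carbonic anhydrase.

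Of 26463 genes tested, 956 passed an adjusted p of 0.05 by limma-trend, 627 higher and 329 lower in the depleted tumours. The rises with the largest fold changes were in Hpca, a neuronal calcium sensor (chr4:129111570-129122036; 70.4 ± 89.8 to 2070 ± 1721 normalized counts, SD, n = 4 each; log2 fold change 5.15, SE 0.77, adjusted p = 0.00917), and Slc17a7. The latter is the vesicular glutamate transporter of excitatory neurons (chr7:45163949-45176142; log2 fold change 5.05, SE 1.03, adjusted p = 0.0186). Cck, Vsnl1, Eef1a2, Nrgn, Snap25, C1qtnf4 and Cend1, most of them expressed by neurons, were among those that followed with log2 fold changes from 4.99 down to 4.20. Among the falls, Acan (chr7:79053483-79115099) went from 5615 ± 6568 to 374 ± 281 normalized counts (SD, n = 4 each; log2 fold change -3.47, SE 0.81, adjusted p = 0.0291). Car9 (chr4:43506966-43513729) went from 140 ± 84.8 to 15.1 ± 15.2 (log2 fold change -3.37, SE 0.75, adjusted p = 0.0244). H2-Eb2 (-3.33) and H2-M3 (-3.05), both of the major histocompatibility complex, Apol9b (-3.22) and Car6 (-3.04), another carbonic anhydrase, completed the 10 largest. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had log2 fold changes of -5.28, -5.20, -4.93 and -4.88, and together 33 reads in the 4 depleted libraries against 1574 in the 4 controls. In 1919 genes (7.25%) the 2 groups of libraries did not overlap, where chance gives 2.86%.

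Macrophage and immune lists fell together. Of the 24 TAM genes, 4 fell over all genes tested and 19 adjusted over the list alone, with a median log2 fold change of -1.39 (camera adjusted p = 7.94e-10). The 4 were Adgre1, which encodes the macrophage marker F4/80 (334 ± 99.7 to 84.2 ± 54.1 normalized counts, SD, n = 4 each; log2 fold change -2.10), the pan-leukocyte gene Ptprc (-1.75), Fcer1g (-1.69) and Cd14 (-1.87). The TAM list had an adjusted p = 0.272 with an estimated correlation. Single macrophage genes fixed beforehand did not pass over all genes. Csf1r, the receptor macrophages need to survive, had a log2 fold change of -1.10 (SE 0.45, adjusted p = 0.194). C1qa had -1.39 (adjusted p = 0.117), Aif1 -1.42 (adjusted p = 0.0548), Cd68 -1.06 (adjusted p = 0.241) and the monocyte receptor Ccr2 -1.92 (adjusted p = 0.0604). The microglial genes Tmem119 and P2ry12 had log2 fold changes of -0.82 (adjusted p = 0.464) and -0.58 (adjusted p = 0.593). All 10 genes of the microglia list were lower, with a median of -0.48, and that list did not pass (camera adjusted p = 0.107). The monocyte list of 10 genes fell (median -1.84, camera adjusted p = 0.00181, 0 genes past over all genes, and 5 lower and 1 higher adjusted over the list alone; adjusted p = 0.348 with an estimated correlation).

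Antigen presentation was lower as well. All 7 genes of the MHC class II list, which leaves out H2-Eb2, were lower, with a median log2 fold change of -3.41 (camera adjusted p = 3.52e-05; 0 past over all genes and 7 adjusted over the list alone; adjusted p = 0.348 with an estimated correlation). All 11 MHC class I genes were lower too, with a median of -1.81 (camera adjusted p = 3.09e-05; 7 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation). Over all genes 2 of them fell, the classical heavy chain H2-D1 (log2 fold change -2.26) and the peptide-trimming enzyme Erap1 (-1.30). Of 30 interferon response genes, 27 were lower, with a median of -1.05 (camera adjusted p = 4.62e-06; 0 past over all genes and 6 adjusted over the list alone; adjusted p = 0.371 with an estimated correlation). The inflammatory NF-kB list of 17 genes fell by a median of 1.02 (camera adjusted p = 0.000159; adjusted p = 0.255 with an estimated correlation), with Birc3 past over all genes and 5 genes adjusted over the list alone. Lymphocyte and other leukocyte markers also fell. The T cell list did so by a median of 1.55 (12 of 12 lower, camera adjusted p = 3.52e-05). The B cell list fell by 1.54, neutrophil by 1.59, NK cell by 1.25, dendritic cell by 1.23 and checkpoint genes by 1.05 (camera adjusted p from 0.0115 to 0.0258). Over all genes only Cd86, in the checkpoint list, passed among these. In all, 7 T cell genes, 2 B cell, 1 neutrophil, 0 NK, 1 dendritic and 2 checkpoint genes did so adjusted over the list alone. The 6 lists had an adjusted p of 0.353 with an estimated correlation, except 0.371 for NK cells. Several of these lists also follow the background reads. Between the high- and the low-background Type 2 libraries the median difference was 3.36 for neutrophil, 1.68 for B cell, 1.22 for NK cell, 0.96 for T cell and 0.89 for dendritic cell genes. The receptor genes themselves fell after depletion, by a median of 0.52 within the high- and 1.24 within the low-background libraries, so background is not fully separated from these falls.

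The neuron list rose as a whole: all 15 genes were higher, with a median log2 fold change of 3.79 (camera adjusted p = 6.31e-16). Over all genes 8 rose, among them Snap25, Slc17a7, the neuronal nuclear protein Rbfox3 (3.30) and the synapsin Syn1 (3.66), and 15 adjusted over the list alone. The list had an adjusted p = 0.255 with an estimated correlation. The astrocyte list rose by a median of 1.49 (12 genes, camera adjusted p = 7e-05; Aqp4, the astrocyte water channel, at 2.04 past over all genes and 3 genes adjusted over the list alone). It had an adjusted p = 0.352 with an estimated correlation. The mature oligodendrocyte list rose by 1.18 (11 of 11 higher, camera adjusted p = 0.000196; 0 past over all genes, 2 adjusted over the list alone; adjusted p = 0.353 with an estimated correlation). Tumour-associated programmes fell. In the mesenchymal list (17 genes, median -0.87, camera adjusted p = 7e-05; 2 past over all genes and 3 adjusted over the list alone) Anxa2 (-1.61) and Runx1 (-1.53) fell. In the hypoxia and glycolysis list (15 genes, median -0.53, camera adjusted p = 0.000926; 4 and 6) Car9, Ankrd37 (-1.89), Egln3 (-1.81) and the angiogenic factor Vegfa (-1.65) fell. In the fibroblast matrix list (13 genes, median -1.24, camera adjusted p = 0.000623; 1 and 5) periostin, Postn, fell (-2.24). The TAM-to-tumour ligand list (12 genes, median -0.68, camera adjusted p = 0.0258; 1, Vegfa, and 3) and the proliferation list (20 genes, median -0.76, camera adjusted p = 0.0115; 0 and 0) fell too. With an estimated correlation these 5 lists had adjusted p = 0.255, 0.348, 0.348, 0.272 and 0.577. The lists that did not pass were mural cells (median -0.55), endothelial cells (-0.36), oligodendrocyte precursors (-0.41), neural stem cells (0.16), cholesterol synthesis (0.20), ER stress (0.30), erythroid genes (-1.21), immediate early genes (-0.23), myeloid recruitment (-0.16) and the 5 glioma driver genes (0.51). Their camera adjusted p ran from 0.0596 to 0.558. In these, Sox10 (-2.01), Ier3 (-2.41) and Postn were past over all genes.

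Within the high-background and the low-background Type 2 libraries, 2 depleted against 2 control each, the neuron list had medians of 3.60 and 4.25, the astrocyte list 1.91 and 1.02, and the oligodendrocyte list 1.24 and 1.36. The immune lists kept their sign in both sets with smaller medians in the high-background libraries. They were -0.56 and -2.10 for the TAM list, -2.47 and -4.36 for MHC class II, -1.23 and -2.71 for MHC class I. They were -0.49 and -1.69 for interferon response, -0.93 and -2.61 for T cells and -0.85 and -2.09 for monocytes. The proliferation list turned, with 0.04 and -1.64, and the microglia list too, with 0.05 and -1.21. Mean levels of the proliferation list were 9.01, 6.74, 9.44 and 7.53 in TAM depleted 1, 2, 3 and 4. In the controls they ran from 7.96 to 9.68, so the fall was not shared by all depleted tumours. The TAM score differed by -0.59 and -1.98 (exact permutation p = 0.333 in both, the smallest that 2 against 2 allow). Leaving out any one library gave an exact p of 0.0571, the smallest possible there. The 956 genes depended on single libraries. Without Type 2 Control 3 there were 100, without TAM depleted 2 and 1 there were 285 and 302, and without Control 1 there were 605. With the background set as a block there were 2635, and in the high-background libraries alone 573. By limma-trend there were 0 in the Type 2 table alone (3194 at an unadjusted p under 0.05), 0 with background subtracted (2933) and 0 in the low-background libraries alone (3669). Upper quartile scaling moved the median over all genes from -0.21 to -0.41 and the split of calls from 627 higher and 329 lower to 674 and 618. With limma-voom the split was 653 and 595. Falls outnumbered rises with library quality weights (130 higher and 306 lower), without TAM depleted 2 (127 and 158) and without Control 1 (285 and 320).

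**Figure D2:**
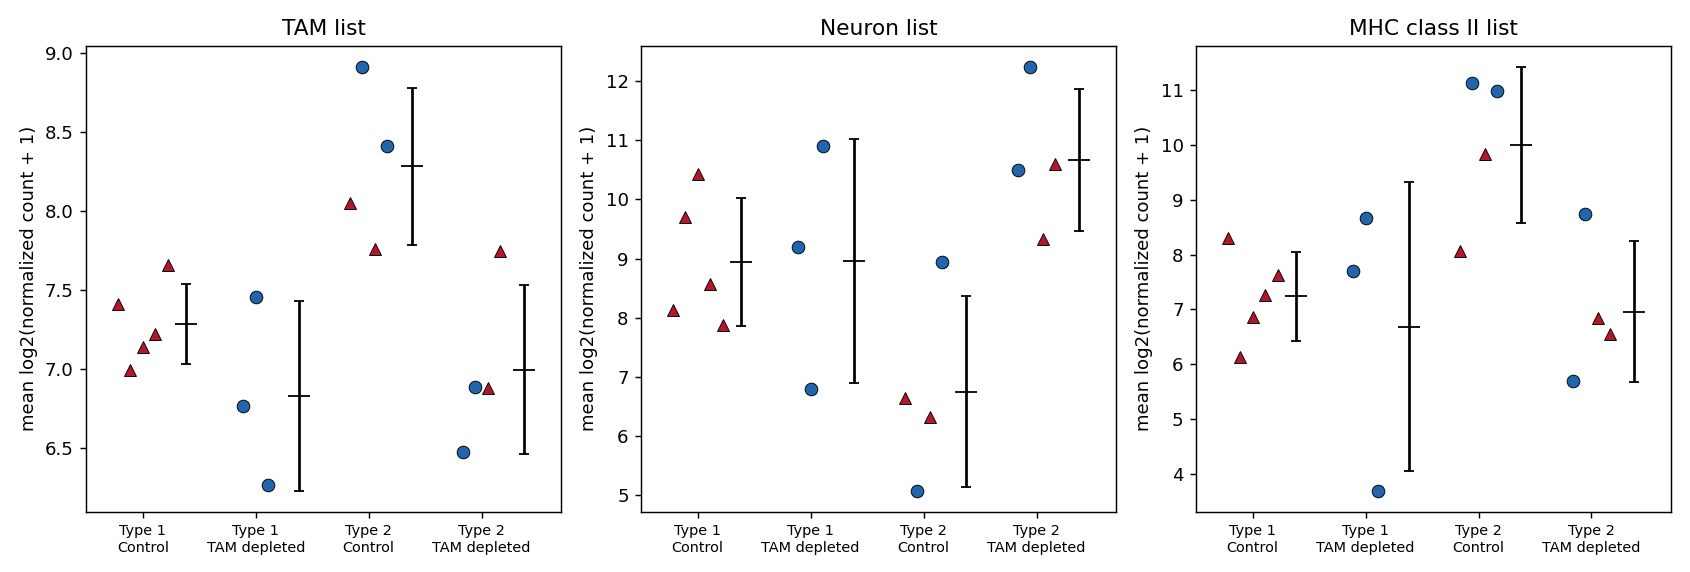
Mean log2(normalized count + 1) of the TAM list (24 genes), the neuron list (15 genes) and the MHC class II list (7 genes) in each library, by group. Triangles are high-background and circles low-background libraries, and bars are mean ± SD. In Type 2 the TAM score fell from 8.28 ± 0.50 in controls to 7.0 ± 0.54 in depleted tumours.

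For Type 1, the same comparison of TAM depleted with Control tumours gave lower T and NK cell and higher cell cycle lists at the preset correlation, none of which held with an estimated correlation (adjusted p = 0.772 each), and no single gene past the threshold. The TAM score was 6.83 ± 0.60 (SD, n = 3) after depletion and 7.29 ± 0.26 (SD, n = 5) in controls, a difference of -0.45 that the spread between libraries allows (2-sided exact permutation p = 0.25). The T cell list (12 of 12 genes lower, median log2 fold change -1.76, camera adjusted p = 0.0121) and the NK cell list (8 of 8 lower, median -2.12, camera adjusted p = 0.0136) fell at the preset correlation and not with an estimated one (adjusted p = 0.772). Both lists also stood higher in the high-background Type 2 libraries, by medians of 0.96 and 1.22. The B cell, neutrophil, dendritic cell and monocyte lists did not pass (camera adjusted p from 0.0818 to 0.0965). The proliferation list (20 of 20 higher, median 0.71, camera adjusted p = 0.00339), the ER stress list (12 of 12 higher, 0.77, 0.00829), the hypoxia and glycolysis list (12 of 15 higher, 0.73, 0.0105) and the cholesterol synthesis list (13 of 15 higher, 0.48, 0.0287) rose. In all 6 lists 0 genes passed over all genes by limma-trend. Adjusted over the list alone, 4 T cell and 5 NK genes did, and 0 of the other 4 lists. The other 4 also had an adjusted p = 0.772 with an estimated correlation.

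None of the macrophage genes fixed beforehand passed in Type 1. Csf1r (chr18:61100598-61132149) stood at 253 ± 98.1 normalized counts in controls (SD, n = 5) and 180 ± 57.6 in depleted tumours (SD, n = 3), a log2 fold change of -0.46 (SE 0.46, limma-trend adjusted p = 0.478). C1qa (-0.09, adjusted p = 0.903), Aif1 (-0.26, adjusted p = 0.657), Cd68 (0.13, adjusted p = 0.862), Tmem119 (-0.75, adjusted p = 0.358) and P2ry12 (-0.62, adjusted p = 0.421) did not pass either. Ccr2 had the lowest p of the fixed genes (60.9 ± 5.29 to 21.2 ± 9.53 normalized counts; log2 fold change -1.56, SE 0.56, adjusted p = 0.105). With background subtracted Ccr2 turned to 2.61 (limma-trend adjusted p = 0.435), a setting that also moved the median over all genes. The fall of Ccr2 is therefore not separated from background reads. The mean of the monocyte list fell by 1.21 log2 units, from 6.33 ± 0.14 (SD, n = 5) to 5.12 ± 0.93 (SD, n = 3; exact permutation p = 0.0357, the smallest possible), while its camera test did not pass (adjusted p = 0.0965). Depleted tumour 3 stood at 4.05 and the others at 5.59 and 5.71. The mean of the microglia list was 6.62 ± 0.43 in controls and 6.02 ± 0.83 in depleted tumours (exact permutation p = 0.179). For the lists of MHC class II, MHC class I, interferon response and neurons the medians were -0.66, 0.33, -0.36 and 0.06, and none passed (camera adjusted p from 0.188 to 0.979). The mean of the MHC class II list was 3.71 in depleted tumour 3 and 7.70 and 8.66 in depleted 1 and 2. The median, mean and test differed in sign for the mesenchymal and erythroid lists.

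By limma-trend 0 genes passed in Type 1, with 8019 at an unadjusted p under 0.05 (1537 higher and 6482 lower), 0 by limma-voom and a lowest adjusted p of 0.0918. In 10353 genes (39.1%) the groups of libraries did not overlap, where chance gives 3.57%. Every Type 1 control was high-background and every depleted tumour low-background, so neither set held both groups. With the background set as a block, which rests on the Type 2 libraries, 0 genes passed by limma-trend (899 at an unadjusted p under 0.05) and 17 lists did, among them the TAM list (median -0.56) and interferon response (-1.09). With that block the proliferation list kept its rise (median 0.62), and the T and NK cell medians shrank to -0.66 and -0.78 and still passed. The ER stress (0.10, camera adjusted p = 0.789) and hypoxia and glycolysis (0.30, camera adjusted p = 0.446) lists lost their calls, and cholesterol synthesis turned to a fall (-0.29, camera adjusted p = 0.0293). With a background covariate these 3 lists did not pass either, and the T and NK cell medians were -0.57 and -0.91. Other settings gave many calls, 13721 with library quality weights and 16381 (6699 higher and 9682 lower) in the Type 1 table alone. That table has its own size factors, its own 29708 tested genes and its own fit. Which of these gave the count cannot be told from this setting. Quality weights kept the size factors and the 26463 tested genes. The main fit shares 1 estimate of the spread over both tumour kinds, and Type 2 in its own table gave 0 genes. The 0 of Type 1 and the 956 of Type 2 therefore do not show which kind responded more. The 6 lists fell to 0 after quantile normalization or background subtraction (with subtraction the T cell median was 0.34 and the NK median -0.40, where that of all genes was 0.76).

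The test of whether the 2 kinds of tumour responded differently, the Type 2 minus the Type 1 response, gave differences in gene lists and none in single genes. The neuron list differed by a median log2 of 3.90 (15 of 15 positive, camera adjusted p = 5.33e-10) and the oligodendrocyte list by 1.68 (camera adjusted p = 0.00353), both more positive in Type 2. None of the 11 lists that passed at the preset correlation held with an estimated one (neuron adjusted p = 0.461, lowest of any list 0.217). More negative in Type 2 were proliferation (-1.48, 20 of 20 negative, camera adjusted p = 1.76e-08), and hypoxia and glycolysis (-1.42, 3.93e-09). So were MHC class I (-2.24, 11 of 11 negative, 2.62e-07), MHC class II (-2.61, 7 of 7 negative, 0.000378) and the TAM list (-0.95, 21 of 24 negative, 1.81e-05). The mesenchymal (-0.81), interferon response (-0.63), oligodendrocyte precursor (-0.43) and immediate early (-0.41) lists also passed (camera adjusted p from 0.000132 to 0.0378). Over all genes 0 of their members passed by limma-trend. Adjusted over the list alone, 13 neuron, 4 hypoxia, 4 MHC class I and 1 each of the mesenchymal, MHC class II, precursor and immediate early genes did. By limma-trend 0 genes passed (2666 at an unadjusted p under 0.05, lowest adjusted p = 0.312; 0 by limma-voom), and the fixed macrophage genes had an adjusted p of 0.502 or more. The Type 1 part of this contrast carries the background difference. With the background set as a block 166 genes and 6 lists passed, the interferon median moving to 0.02 and the immediate early median to 0.31.

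**Figure D3:**
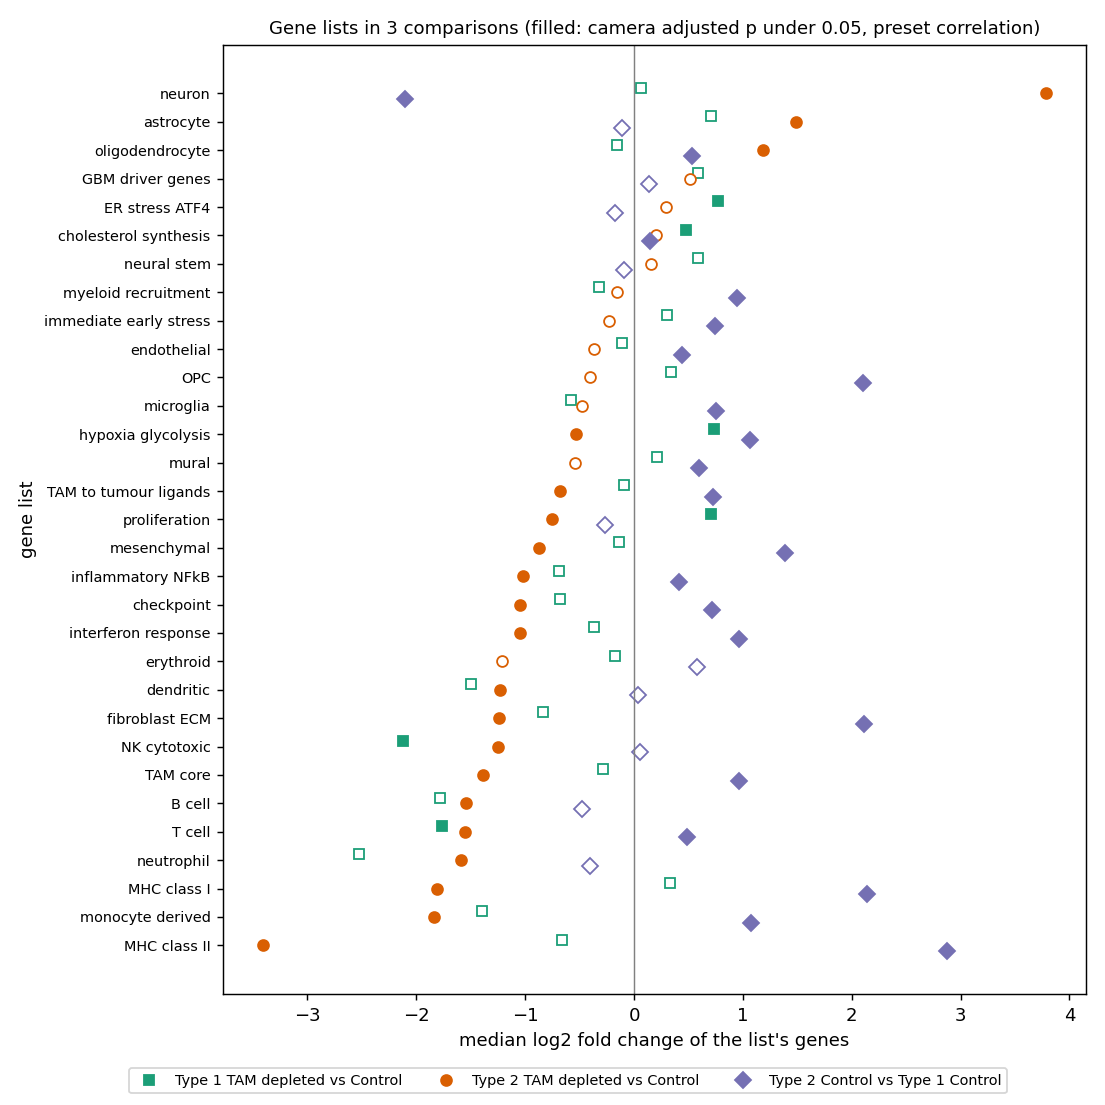
Median log2 fold change of the genes of each of the 31 lists in 3 comparisons (squares, Type 1 TAM depleted against Control; circles, Type 2 TAM depleted against Control; diamonds, Type 2 Control against Type 1 Control). Filled symbols have a camera adjusted p under 0.05 with the preset correlation. The neuron list stands at 3.79 in Type 2 and at 0.06 in Type 1.

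The control tumours alone, Type 2 Control against Type 1 Control, show how the 2 kinds differ before depletion. Type 1 tumours carried extreme levels of Mycn, the neural MYC-family transcription factor (chr12:12936093-12941914), at 24299 ± 15120 normalized counts (SD, n = 5) against 51.7 ± 13.7 in Type 2 (SD, n = 4). It was 388-fold lower in Type 2 (log2 fold change -8.60, SE 0.54, limma-trend adjusted p = 3.73e-07). Its neighbours Ddx1, an RNA helicase (chr12:13216973-13249213; 167-fold lower, log2 fold change -7.38), and Nbas (chr12:13269133-13583811; 78.6-fold lower, -6.30) moved with it. Type 2 tumours expressed oligodendrocyte lineage genes. Sox10, the transcription factor of that lineage (chr15:79154908-79165240), rose from 151 ± 91.0 in Type 1 to 3232 ± 1284 in Type 2 (SD, n = 5 and 4; log2 fold change 4.56, SE 0.49, adjusted p = 9.31e-05). The glial connexin Gjc3 (chr5:137953461-137963098) rose from 177 ± 102 to 4883 ± 1544 (log2 fold change 4.92, SE 0.38, adjusted p = 6.02e-06).

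In this comparison 819 genes passed by limma-trend, 603 higher and 216 lower in Type 2. In 1840 genes (6.95%) the groups did not overlap, where chance gives 1.59%. The other large rises were the matrix genes Acan (4.76), Hapln1 (4.57) and Col11a1 (4.35), Sema3d (4.35), the non-coding RNA Neat1 (4.30), the neuregulin receptor Erbb3 (3.98), complement C4b (3.94) and Susd5 (3.91). The other large falls were Rpl21-ps2 (-7.84), Platr19 (-7.74) and Rpl36-ps3 (-6.02), all on chromosome 12 near Mycn, Crabp1 (-6.21), and the neuroendocrine and neurogenic transcription factors Insm1 (-5.50), Nhlh1 (-5.38) and Neurod1 (-5.29). Rpl21-ps2 and Rpl36-ps3 are pseudogenes, whose reads can be shared with their parent genes. Between 12351522 and 13627646 on chromosome 12, all 22 tested genes passed, 3 of them coding, with log2 fold changes from -8.60 to -5.32, while the 10 genes next to this interval ran from -2.33 to -0.47. The interval was drawn after the values were seen. It was extended from Mycn while genes passed with a large fall, and it ended where several genes in a row did not. That the genes inside passed and those next to it did not therefore follows largely from this rule. The 10 genes next to it are not coding and had means of only 14.6 to 82.9 normalized counts in Type 1 controls, so they say little about an edge. Of the glioma driver genes, Egfr, Nf1, Cdkn2a and Trp53 did not pass. The log2 fold changes were -1.50 for Egfr (adjusted p = 0.359), 0.68 for Nf1, 1.15 for Cdkn2a and 0.12 for Trp53.

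**Figure D4:**
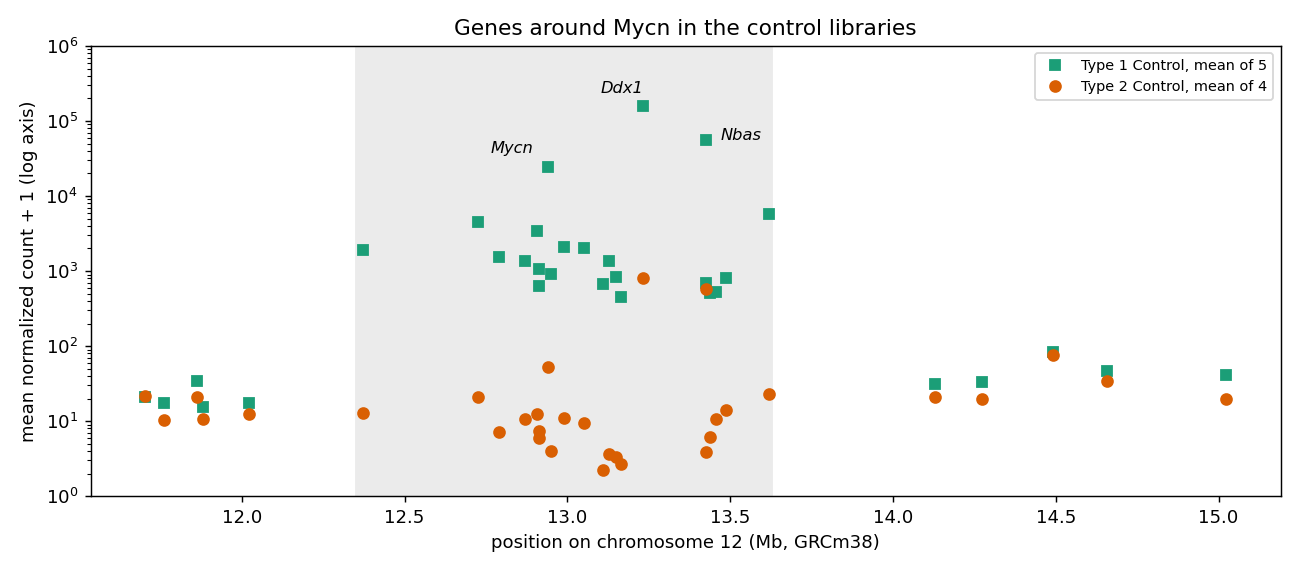
Mean normalized count plus 1 (log axis) of the tested genes on chromosome 12 around Mycn, by position (Mb, GRCm38), in the 5 Type 1 controls (squares) and the 4 Type 2 controls (circles). Shading marks the 22 genes from 12351522 to 13627646 that passed, with Mycn at 24299 in Type 1 and 51.7 in Type 2.

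Of the 31 lists, 20 were higher and the neuron list lower in Type 2 controls. Oligodendrocyte precursor genes had the lowest p at the preset correlation (14 of 14 higher, median log2 fold change 2.10, camera adjusted p = 1.73e-13; adjusted p = 0.072 with an estimated correlation). Of these, 5 were past over all genes and 10 adjusted over the list alone, among them Sox6 (3.29), the proteoglycan Cspg4 (3.68) and the receptor Gpr17 (3.84). In all, 4 lists held with an estimated correlation. Mesenchymal genes (17 genes, median 1.39, 8 past over all genes and 11 adjusted over the list alone; adjusted p = 0.0182 with an estimated correlation) included Anxa2 (2.94), the hyaluronan receptor Cd44 (2.19) and Vim (2.24). The 3 others had an adjusted p = 0.0456 and were fibroblast matrix (median 2.12, 5 and 9; Postn 3.04, Fn1 3.49), hypoxia and glycolysis (1.07, 5 and 8; Ndrg1 2.86, Bnip3 1.68) and the TAM-to-tumour ligands (0.73, 3 and 5; Vegfa 1.94, Hbegf 1.51, Tgfb1 1.30). Of the immune lists, neutrophil (median -0.41), B cell (-0.48), NK cell (0.05) and dendritic cell (0.04) did not pass (camera adjusted p from 0.65 to 0.794). The other immune lists were higher in Type 2. The first was MHC class I (11 of 11, median 2.14; H2-D1 3.02 and H2-K1 2.94 among 3 past over all genes, 10 adjusted over the list alone; adjusted p = 0.115 with an estimated correlation). So were MHC class II (7 of 7, 2.87, 0 and 7; 0.133), interferon response (30 of 30, 0.96, 1 and 6; 0.23) and the TAM list (23 of 24, 0.96, 0 and 12; 0.106). Among the high-background controls alone these medians were 1.22, 1.77, 0.48 and 0.61, and 5 lists lost their calls there: microglia (camera adjusted p = 0.463), checkpoint (0.426), immediate early (0.103), oligodendrocyte (0.268) and cholesterol synthesis (0.693). The proliferation, ER stress and astrocyte lists passed there as lower (camera adjusted p = 0.000929, 0.0136 and 0.0458). The neuron list was lower (15 of 15, median -2.11; Rbfox3 -3.10 and Stmn2 -3.09 among 3 past over all genes, 6 adjusted over the list alone; adjusted p = 0.23 with an estimated correlation). Csf1r (log2 fold change 1.28, adjusted p = 0.132) and C1qa (1.43, adjusted p = 0.108) did not pass as single genes. The median, mean and test differed in sign for the neutrophil, astrocyte and neural stem lists.

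All Type 1 controls and 2 of the 4 Type 2 controls were high-background. Among the high-background controls alone 1057 genes passed (399 higher and 658 lower), 495 of them among the 819. The split of calls moved with the scaling, to 626 higher and 446 lower with upper quartile scaling and 1079 and 725 with quantile normalization. Falls outnumbered rises by limma-voom (902 higher and 1441 lower), with library quality weights (2646 and 3913) and with the background set as a block (482 and 744). Without any one Type 1 control there were 510 to 693 genes, and without any one Type 2 control 524 to 1141. The Type 2 controls also enter the Type 2 depletion contrast, so genes high in these 4 libraries by chance appear as rises here and as falls there.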

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

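The tests of the Y-linked genes, the explanations tested for the neuron list, the receptor-gene comparison for Type 1 and every fit with the background sets were chosen after the values were seen. The gene lists and the splits without background were set beforehand.

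In Type 1, 5543 genes outside the receptor families were lower at an unadjusted p under 0.05 and 1537 were higher, with median log2 fold changes of -2.60 and 0.79. Background reads fit both parts, less clearly for the higher genes. In Type 2, where background is balanced over treatment, the lower genes differed between high- and low-background libraries by a median of 2.73 (quartiles 1.58 to 3.65, higher in 97.6% of genes). The higher genes differed by -0.53, where the 18386 other genes outside the receptor families also stood at -0.24. A response to TAM depletion itself stays open, because the lower genes also had a median of -0.95 in Type 2 within the background sets, yet the receptor genes moved there by -0.88, so the test does not separate the treatment from leftover background. The 3 depleted Type 1 libraries may thus differ from the 5 controls mainly in background, and no Type 1 library separates them, so a block for background has to borrow its effect from Type 2.

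The neuron list was 3.79 higher (median log2) in Type 2 TAM depleted tumours. Background reads are argued against, since the list had a median of 3.60 or more in both background sets. Each group had 2 libraries in each set. The SD of 0.72 over the 15 genes in the set with the lower median does not measure the spread between libraries. More normal brain tissue in the depleted samples remains a candidate explanation: the astrocyte and oligodendrocyte lists rose too, the smaller median being 1.18. The lineage genes high in Type 2 controls were mainly those of precursors (median 2.10 above Type 1 controls). The mature oligodendrocyte list differed there by 0.53, with 2 genes past over all genes, so tumour cells could carry part of it. After depletion the precursor list did not rise with the mature list (median -0.41). A change within tumour cells was not tested.

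The 4 Y-linked genes were lower by a mean log2 of -5.07 (SE 0.66; exact permutation p = 0.0286, the smallest possible) in Type 2 TAM depleted tumours. Loss of Y-bearing macrophages alone is argued against, since the TAM score changed by -1.29, and background is argued against by falls of -4.86 and -5.29 in the high- and low-background sets. A different sex of animals or of transplanted cells between the groups could account for it: 3 of the 4 depleted libraries had 3 or fewer Y-linked reads, while TAM depleted 1 had 30 and the controls 37 to 880. In Type 1 the mean log2 difference was -4.13 (exact permutation p = 0.0714), with 2, 174 and 1 Y-linked reads in depleted 1, 2 and 3 and 64 to 657 in the controls. Xist was present in all 16 libraries at 2979 to 30130 normalized counts, so male and female RNA would have to be mixed in those with Y-linked reads.

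Single libraries stood apart from their group in 11 of 134 groups of values tested, where chance gives about 1 in 20. Type 1 Control 1 had 7.63 M reads against 5.83 to 6.11 M in the others. On the log2(normalized count + 1) scale, Type 2 Control 4 had Vsnl1 at 9.09 (others 4.05 to 4.89) and P2ry12 at 7.71 (6.52 to 6.66), and Type 2 TAM depleted 2 had Cend1 at 10.7 (8.28 to 8.64). Type 2 TAM depleted 1 had Eif2s3y at 1.10 and Ddx3y at 2.14, where the other 3 were at 0. Type 2 TAM depleted 4 had C1qa at 8.97 (7.83 to 7.87). Type 2 Control 3 had Nbas at 8.42 (9.27 to 9.44) and Control 1 had Rpl36-ps3 at 3.03 (2.83 to 2.86). Type 1 Control 5 had Egfr at 7.50 (10.1 to 10.7).

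The responses of the 2 tumour kinds differed in 11 lists by camera with the preset correlation, in 0 with an estimated correlation (lowest adjusted p = 0.217) and in 6 with the background set as a block. The medians of the difference were -0.95 for TAM, -2.24 for MHC class I, -2.61 for MHC class II, -0.63 for interferon response. They were 3.90 for neuron, 1.68 for oligodendrocyte, -0.43 for oligodendrocyte precursor, -1.48 for proliferation, -1.42 for hypoxia and glycolysis, -0.81 for mesenchymal and -0.41 for immediate early genes.

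Other splits of the same libraries were fitted. Between the controls, 1 of 100 drawn of the 126 splits gave as many genes as the 819 of the real one, which was that split itself. The highest other gave 1, so chance is an unlikely source of this count. The splits speak to the count and not to each of the 819 genes. For Type 2 depletion, 3 of 35 splits gave 956 or more, so chance cannot be excluded. The highest other, 9517, put 1 high-background library against 3. It is not the split that separates the background sets, so it does not show that the count follows background alone. Among splits that keep the background balanced, with the background set as a block, 1 of 18 reached the real 2635 and the highest other gave 67, but 18 splits are too few for a share under 0.05. For Type 1 depletion and the difference of responses the real count was 0, which every split reaches (56 of 56, highest other 1, and 100 of 100, highest other 6441), so these splits decide nothing about chance. The split with 6441 genes points to a structure of the samples: it put all 4 high-background Type 2 libraries in 1 group.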

How the results depend on the processing

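Alternatives for background, limma-voom and the deposited values as they are were chosen after seeing the data; the rest were set beforehand. Of the gene counts, list counts and TAM scores under alternatives, 159 kept their direction and side of the threshold or stayed within 1.5 times, 32 counts moved further, 15 scores lost their call, most in settings whose splits allow no p under 0.05, and 1 changed sign. Unless stated, the cause was not tested. The tests of edgeR and DESeq2 were not run, although the recovered whole reads would have allowed them. Depth limits genes with few reads, since 1 read is worth more in the shallow high-background libraries.

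Between the controls the 819 genes became 1804 with quantile normalization, 6559 with quality weights, 2343 by limma-voom, 1283 with the background covariate and 326 with background subtracted (289 shared), and 510 to 1141 with single libraries left out. The 0 genes of Type 1 became 13721 with quality weights and 16381 in its own table, and stayed 0 without any one library. They also stayed 0 with the block for the number series (7550 at an unadjusted p under 0.05 by limma-trend). The 956 genes of Type 2 became 436 with quality weights (327 shared), 0 in its own table (8 libraries fitted) and 0 with background subtracted. They became 0 in the low-background and 573 in the high-background libraries alone (4 Type 2 libraries each), 2635 with the background block, and 100 to 1258 with single libraries left out. The difference of responses went from 0 to 748 with quality weights and 166 with the background block. Subtraction was incomplete: in 16 check genes the observed background was 1.72 to 3.93 times the predicted.

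The list count of Type 1 went from 6 to 10 with the filter of 50, 0 with quantile normalization, 13 with the covariate, 0 with subtraction and 17 with the background block. With an estimated correlation it was 0 in Type 1, 0 in Type 2, 0 for the difference of responses and 4 between the controls; the background block left 6 for the difference.

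The TAM score difference in Type 1 turned to 0.17 with background subtracted (exact p = 0.679), where the median over all genes also moved, from -0.06 to 0.76. It lay from -0.77 to -0.17 with single libraries left out. In Type 2 it kept its sign and lost its call as the microglia list (-0.55, exact p = 0.257), without Apoe, Cd14 and Cd163 (-1.35, 0.0571), in its own table (-1.27, 0.0571) and with subtraction (-1.24, 0.0857). It also did so in the low- and high-background sets (-1.98 and -0.59, 0.333 each, the smallest possible) and from -1.54 to -1.08 with single libraries left out (0.0571, the smallest possible).

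Whether the sample numbers pair the samples cannot be told from the values. In the labels the numbers follow the order in which the samples of a group are listed, and nothing there states a pairing. Same-numbered samples correlated at -0.05, -0.16 and 0.37 in Type 1 and -0.68, 0.50, 0.30 and -0.60 in Type 2. Not every sample correlated best with its own number. In Type 2 the positive values joined libraries of the same background set and the negative ones libraries of different sets. The signs there follow background and decide nothing about pairing. With the replicate block the counts were 0 in Type 1, 286 in Type 2 (268 shared), 0 for the difference and 822 between the controls. The Type 2 TAM difference of -1.29 had an exact p = 0.125, the smallest that 4 pairs allow. C1qa in Type 1 turned to 0.0766 and Tmem119 in the difference to 0.22.

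Single genes that turned sign did not pass in either setting. Upper quartile scaling moved the median over all genes from -0.06 to -0.44 in Type 1 and from 0.16 to 0.34 for the difference, so turns under it are no evidence on a single gene. The same holds for subtraction in Type 1. In Type 1, Aif1 went to 0.57 with quantile normalization, 0.0647 in its own table and 0.48 with subtraction. Cd68 went to -0.12 with quantile normalization, -0.27 with upper quartile scaling, -0.31 with the background block and from -0.50 to 0.65 with single libraries left out. C1qa went to 0.24 in its own table and from -0.63 to 0.19 with single libraries left out. With subtraction P2ry12 went to 0.0839 and Ccr2 to 2.61. In Type 2, P2ry12 went to 0.0325 in the high-background libraries. For the difference of responses, P2ry12 went to -0.18 with quantile normalization, -0.25 with quality weights, -0.0125 with the deposited values, -0.10 by limma-voom, -0.14 with the covariate, -0.35 with subtraction, -0.11 with the background block and from -0.40 to 0.55 with single libraries left out. Tmem119 went to 0.11 with upper quartile scaling, 0.15 with the covariate, 0.33 with the background block and from -0.52 to 0.78 with single libraries left out. Csf1r went to 0.19 with the background block and Ccr2 from -0.70 to 0.34 with single libraries left out. Named genes called between the controls kept their call in 499 gene and setting pairs and lost it in 1, and those without a call gained one in 9 pairs and stayed without in 166. In Type 2 called genes kept it in 360 and lost it in 137 pairs, and the others gained it in 16 and stayed without in 158, with 1 sign change.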

Other observations

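The test of the chromosome 12 interval was chosen after the values were seen, and so were the comparisons with it.

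Mycn and Ddx1, both in the chromosome 12 interval, stayed high in Type 1 tumours after depletion. Mycn stood at 30910 ± 11680 normalized counts in Type 1 TAM depleted tumours (SD, n = 3) and 24299 ± 15120 in controls (SD, n = 5), and Ddx1 at 301800 ± 149800 and 157800 ± 107100. Mycn was lowest in Type 1 Control 3 (5923) and highest in Control 5 (46870). Type 2 TAM depleted 4 had Mycn at 466 and Nbas at 1982 normalized counts, where the other 7 Type 2 libraries had at most 108 and 973. The gap junction gene Gjc3, high in Type 2 controls, stood at 1388 ± 257 normalized counts in Type 2 TAM depleted tumours (SD, n = 4) against 4883 ± 1544 in controls (SD, n = 4).

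Extra genomic copies of the interval in Type 1 tumour cells are a hypothesis. Its 5 processed pseudogenes, which are seldom transcribed from their own promoters, had a median of 128 times the background rate per kilobase in the 5 Type 1 controls (46.7 to 352) and 0.39 and 2.12 times (median 1.25) in the 2 high-background Type 2 controls. The 2 high-background Type 2 TAM depleted libraries had 1.64 and 6.06 times. The low-background Type 1 TAM depleted libraries had a median of 786 times and the 4 low-background Type 2 libraries 6.09 to 28.8 times. The ratio is thus also high where background is low, and read-through transcription could give the same values. Only 2 of the 5 pseudogenes lie clear of other genes, and the kit does not mark strand, so reads of host genes such as Nbas enter these rates. Per 1000 normalized counts of Nbas, the pseudogenes had 51.0 to 76.7 in the Type 1 controls and 15.1 to 23.2 in the depleted libraries. By this measure they were higher where background was high, unlike the ratio to the background rate. Copies and transcription cannot be told apart by these measures.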
